A study of Homo sapiens with 6 samples.

How the data were processed

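Bulk RNA was sequenced from cardiomyocytes grown from the H1 human embryonic stem cell line carrying dCas9-KRAB, an inactive Cas9 fused to a repressor domain, which silences the promoter that a guide RNA directs it to (CRISPR interference). Of the 6 libraries, 3 came from cells with guides against LINC01629, called knockdown 1 to 3, and 3 from cells with non-targeting guides, called control 1 to 3. Cells were harvested after 60 days of maturation. Per the labels, RNA was purified by column, total RNA libraries were made with a stranded kit that depletes ribosomal RNA, and each sample was sequenced in paired reads. The labels number the replicates but do not say whether they were separate differentiations, so the p-values measure the spread between samples as they were numbered.

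The deposited table held 60609 Ensembl gene rows and a column for each library. Its values were estimated counts per gene (expected counts), not scaled for depth, made by the authors with kallisto on the human build hg38, whose versions are not stated. All values were whole numbers, with 0 exceptions, so the estimates were taken as rounded by the authors; how transcripts were summed to genes, and with which strand setting, is not stated. Antisense and overlapping genes therefore cannot be separated by strand with certainty. The sum per library was 18146313 to 23044321 counts. No molecular identifiers were used, so the 95% Poisson intervals given for single low counts cover counting error only.

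Symbols were present for 60295 rows (99.5%). Coordinates and gene classes were taken from the GENCODE 29 reference annotation (GRCh38), which held 58502 of the rows (96.5%). Of all rows, 21946 were at 0 in every library, and 45 repeated genes of the X chromosome's pseudoautosomal region on the Y chromosome. No library was left out, and no row was removed before the low count filter.

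Genes were tested with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr, library sizes were summed again over the genes kept, TMM factors were applied, and a quasi-likelihood fit with robust dispersion compared knockdown with control, with group as the only term. Changes are log2 fold changes, knockdown minus control, with a standard error (SE) taken from the fold change and the F statistic, and n = 3 per group throughout. P-values were adjusted by the Benjamini-Hochberg method over the 18846 genes kept, and 0.05 was the threshold. Levels are CPM, the usual scaling of counts by library size (with TMM factors, except for LINC01629, which was scaled to all counts of its library), with their SD. In total 46 gene lists, with 865 distinct genes, were written before the data were examined, as were the tests, the threshold and the rule for naming genes. Lists with at least 5 genes kept were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, two-sided, adjusted over the 45 lists tested. A list's score in a library is the mean log2 CPM of its members. Medians and means of lists are of differences in log2 CPM. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Within each list, the edgeR p-values of its members were also adjusted over the list alone.

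The naming rule took LINC01629 and its listed neighbours, then genes past the threshold, or the 10 genes of smallest p where fewer than 5 passed, then up to 2 genes of smallest p per list where none passed over all genes, and 9 cardiomyocyte genes in any case. Other list members that passed over the list alone, and other members or genes given as values, were named after their values were seen. Some genes that the rule would name are not reported here, and the counts of lists include them. The guides' sequences were not used here.

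The alternatives were DESeq2 1.42.0, limma-voom, other scalings (DESeq2 size factors, upper quartile, library size), other filters (none, or a CPM of at least 1 in 3 libraries), protein-coding genes only, removal of mitochondrial and ribosomal RNA genes, a replicate block, other thresholds and each library left out in turn. Chosen after seeing the data were limma-voom with sample quality weights (weighted limma-voom), a fit without knockdown 1 and control 2, lists without shared members, and upper quartile scaling for lists. The replicate numbers were checked as pairs: after removal of group means, same-numbered knockdown and control libraries correlated across genes at 0.354, 0.231 and -0.061 for numbers 1, 2 and 3. The rule set before the data were examined asked for every pair above 0.1, so the samples were not treated as paired.

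The pipeline was tested on simulated data with the spread of these libraries and 100 genes changed at each fold. edgeR called 24% of genes changed 2-fold and 75% of genes changed 4-fold, with 8 false calls; DESeq2 called 41% and 85%, with 53 false calls. A simulated shift of 1 log2 unit in the glycolysis list was called by camera, by camera with an estimated correlation and by fry, with 0 of the 44 other lists called. The simulated genes were drawn independently, and no simulated library stood apart. This therefore does not test false calls of lists whose genes move together. In the real libraries the estimated correlation reached 0.867, in the cytosolic ribosomal protein list. Tables and plots were made with python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.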

Results

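The libraries were made from human stem-cell-derived cardiomyocytes in which LINC01629, a long non-coding RNA gene, was silenced by CRISPR interference, within work on genes near atrial fibrillation risk variants. The comparison asked which transcripts differed from cells with non-targeting guides. Total counts were 20907439, 20455248 and 18146313 in knockdown 1, 2 and 3, and 19771854, 18771242 and 23044321 in control 1, 2 and 3. The cardiac muscle gene TTN alone took 4.08% to 8.82% of the counts of a library. A pair of libraries stood apart from their groups. Knockdown 1 had a mean correlation across genes of 0.949 with the other knockdown libraries and 0.965 with the controls, while knockdown 2 and 3 correlated with each other at 0.982. Control 2 had 26388 genes detected, against 29341 to 30684 in the other 5 libraries, and 0.410% of its counts lay on the mitochondrial chromosome, against 0.209% to 0.295%. Genes are not independent replicates, so these correlations carry no p-value.

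LINC01629 (ENSG00000258602.1), a lincRNA on the plus strand of chromosome 14 from 76959638 to 76965802 (GRCh38), was lower in every knockdown library than in any control. It had 1, 2 and 1 counts in knockdown 1, 2 and 3, against 10, 15 and 24 in control 1, 2 and 3. The level was 0.0669 ± 0.0270 CPM (SD, n = 3) in the knockdown and 0.782 ± 0.268 CPM in the control. Over all libraries, 4 counts against 49 gave a knockdown level of 8.45% of control, with a 95% counting interval of 2.21% to 23%. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 fold change of -3.44 ± 0.70 (SE), with an adjusted p of 0.313 over all genes and 0.0189 adjusted over the list alone (LINC01629 and its neighbours). An exact two-sided permutation test of CPM gave p = 0.1, the smallest that 3 against 3 allows. The lincRNA AC007686.4, on the minus strand from 76958098 to 77000609, overlaps the whole gene and had 0 to 6 counts per library.

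**Figure D1:**
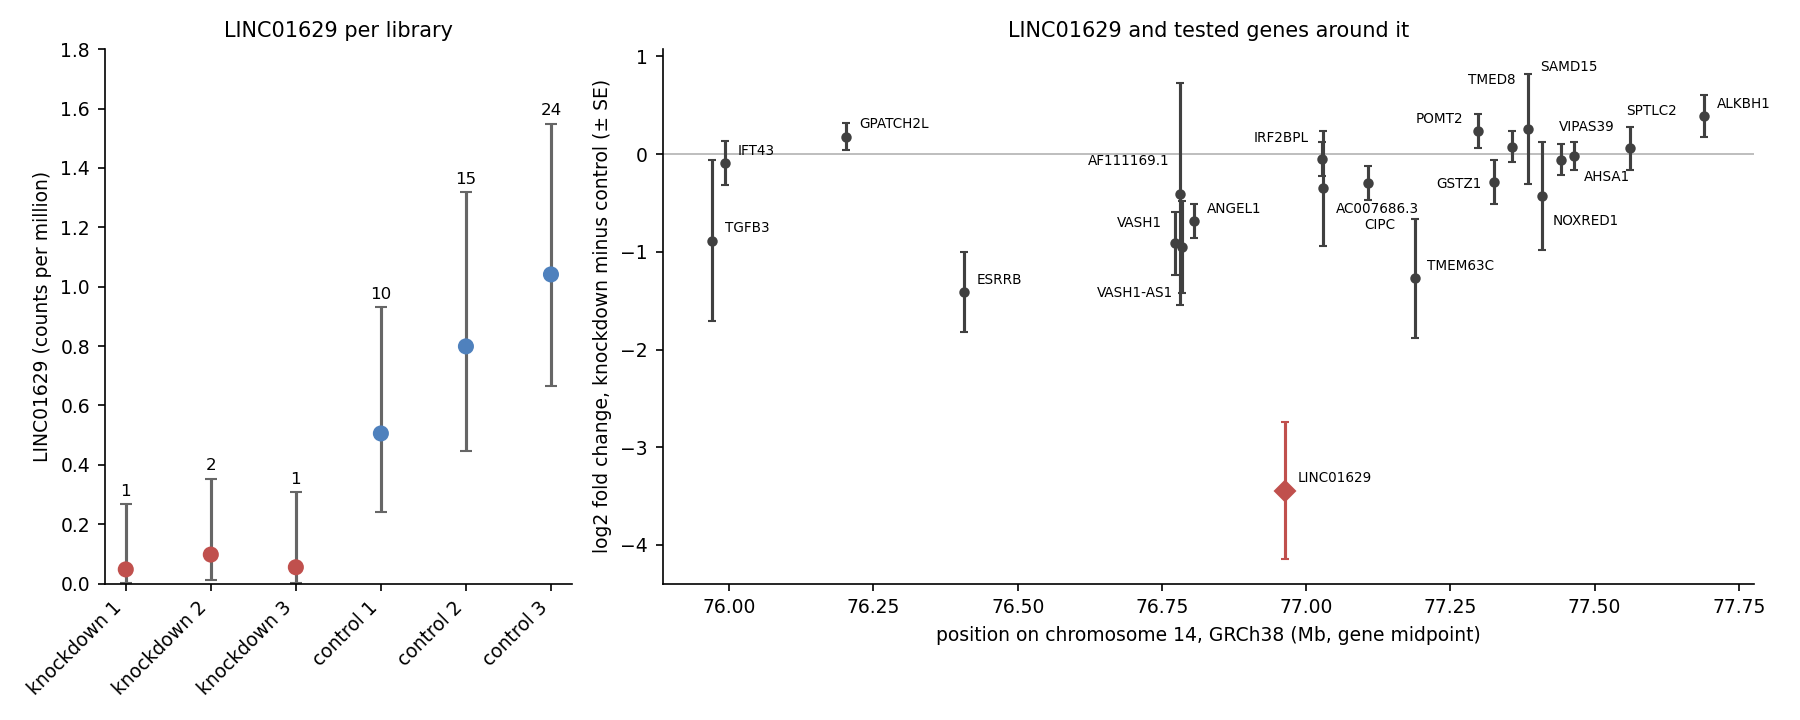
LINC01629 level per library in CPM (counts printed above) with 95% Poisson intervals, and log2 fold changes (± SE) of LINC01629 (red) and tested genes around it on chromosome 14 by gene midpoint in Mb. The knockdown libraries lie at 0.0478, 0.0978 and 0.0551 CPM and the controls at 0.506, 0.799 and 1.04 CPM.

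Among the genes near LINC01629, ANGEL1, VASH1 and ESRRB had the smallest p-values, and all 3 had negative fold changes. ANGEL1, whose nearest end lies 133.4 kb away, was at 14.1 ± 1.90 CPM (SD, n = 3) in the knockdown and 22.7 ± 2.28 CPM in the control (log2 fold change -0.69 ± 0.17). VASH1, which encodes the tubulin carboxypeptidase vasohibin 1, lies 176.6 kb away and had -0.91 ± 0.32. Its groups overlapped, with knockdown 1 at 53.8 CPM and control 2 at 48.0 CPM. ESRRB, which encodes an orphan nuclear receptor, lies 457.8 kb away and had -1.41 ± 0.41. The nearest tested coding gene, IRF2BPL at 58.7 kb, had -0.05 ± 0.18, and CIPC on the same side had -0.30 ± 0.17. Of the 18 neighbours tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 over all genes, 3 were at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Adjusted over the list alone, ANGEL1 passed beside LINC01629 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0331), and had 0.0628 over the neighbours without LINC01629. That count of 2 became 0 without knockdown 2, knockdown 3, control 2 or control 3 and under the filters that removed LINC01629, 4 without knockdown 1 or by DESeq2, and 5 with the replicate block or by weighted limma-voom. Weighted limma-voom called ANGEL1, VASH1 and ESRRB lower (3 genes). As a list, LINC01629 and its neighbours were lower by camera (adjusted p = 0.0400, median -0.11), with adjusted p = 0.572 with an estimated correlation. This list holds the silenced gene itself, so its call is not one for the neighbours alone. The call ended under the filter of a CPM of at least 1, which removed LINC01629 among others (0.261, median -0.06). It also ended without knockdown 3 (0.0933), control 1 (0.0638), shared members (0.0611) or both knockdown 1 and control 2 (0.0575). The list's score was 3.39, 3.15 and 3.04 in knockdown 1, 2 and 3 and 3.46 to 3.72 in the controls. VASH1-AS1 overlaps the ends of VASH1 and ANGEL1.

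Across all genes, the 10 smallest p-values belonged to HCN4, DENND2A, MT1E, CADM3, CACNA1D, FOXP2, SORCS3, GRIK1, XIRP1 and CAPN3. HCN4, the main channel of the pacemaker current, was at 44.6 ± 8.37 CPM (SD, n = 3) in the knockdown and 117 ± 15.5 CPM in the control, a log2 fold change of -1.39 ± 0.18. CACNA1D, an L-type calcium channel of sinoatrial cells, was at 39.7 ± 7.63 and 126 ± 34.4 CPM (-1.66 ± 0.24). CADM3, a cell adhesion gene, had -4.04 ± 0.57, the glutamate receptor gene GRIK1 -3.51 ± 0.54, the protease gene CAPN3 -2.73 ± 0.39, the transcription factor gene FOXP2 -1.88 ± 0.29 and DENND2A -1.77 ± 0.23. CADM3 was at 0.132 ± 0.0985 CPM in the knockdown and 2.29 ± 0.372 in the control, and GRIK1 at 0.252 ± 0.0360 and 2.94 ± 1.64. The size of their falls rests on few knockdown counts. The metallothionein gene MT1E had 2.84 ± 0.39, the sorting receptor gene SORCS3 2.11 ± 0.31, and XIRP1, an actin-binding gene of the intercalated disc, 1.05 ± 0.16. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment each had an adjusted p of 0.272, so these are values and not calls. edgeR called 0 of 18846 genes, with 1866 at an unadjusted p under 0.05 (920 higher, 946 lower) where 942 would be expected by chance alone. Other splits of the 6 libraries gave 122 to 4058 such genes, so an excess over 942 is not particular to the knockdown. DESeq2 called 363 (152 higher, 211 lower), but in the simulation it made 53 false calls against 8 by edgeR. The simulation used edgeR's dispersions, so it does not give the share of the 363 that is false. By limma-voom 0 were called, and by limma-voom with sample quality weights 1478 (578 higher, 900 lower), of which 323 were shared with DESeq2. Without knockdown 1 edgeR called 554, and without knockdown 1 and control 2 it called 2581. Both libraries were left out together because they stood apart from their groups, so the 2581 is not independent of that choice. The quality weights were also lowest for these libraries (0.429 for knockdown 1 and 0.464 for control 2). The groups did not overlap in 2795 genes (14.8%), where chance gives 10%. Genes are not independent, so this excess alone does not show an effect of the knockdown.

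**Figure D2:**
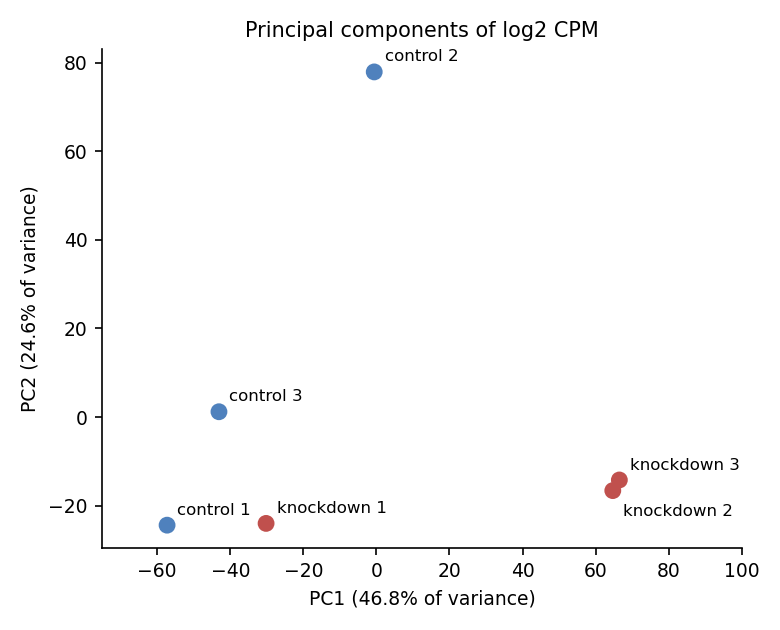
Principal components of log2 CPM for the 6 libraries (knockdown red, control blue), with the first (46.8% of the variance) against the second (24.6%). Knockdown 1 lies at -30.2 on the first component, on the side of control 1 and control 3, and control 2 lies at 77.9 on the second.

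Genes that mark pacemaker-like cells were lower in the knockdown libraries as a group. Of the 14 members, 12 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Beside HCN4 and CACNA1D, the genes that fell included CACNA1G, a T-type calcium channel (20.3 ± 1.87 against 33.6 ± 5.62 CPM; -0.73 ± 0.17), TBX3, a repressor of the working-muscle program (-1.34 ± 0.33), SHOX2, a transcription factor of the sinus node (-3.46 ± 1.25), and ISL1 (-1.97 ± 0.69). The signalling genes RGS6 (-2.82 ± 0.63) and BMP4 (-1.93 ± 0.56), VSNL1 (-2.94 ± 0.80) and the gap junction gene GJC1 (-0.66 ± 0.21) also fell, and CNTN5, an adhesion gene, rose (1.46 ± 0.40). The adjusted p-values of the 13 lay between 0.000546 and 0.0408 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list alone, and without control 3 the count was 6. The score was 4.46, 3.27 and 3.29 in knockdown 1, 2 and 3, below the controls at 5.31, 5.23 and 5.87. Camera gave an adjusted p of 4.47e-10 (median log2 difference -1.81), called under every left-out library, and adjusted p = 0.572 with an estimated correlation; fry gave 0.180. The fibroblast score also differed, at 6.25 in knockdown 1, 4.69 in knockdown 2 and 4.46 in knockdown 3, against 6.15 to 6.80 in the controls. Of the 14 members, 9 are also in another list.

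Atrial cardiomyocyte markers were lower as well, with 7 of 18 members lower when adjusted over the list alone and 0 over all genes. They were TBX5, a transcription factor of atrial identity and rhythm (-1.58 ± 0.27), PLCB1 (-1.86 ± 0.31), the atrial gap junction gene GJA5 (8.68 ± 3.11 against 31.2 ± 15.8 CPM; -1.85 ± 0.46), NR2F2, a regulator of atrial identity (-2.42 ± 0.67), HEY1 (-0.97 ± 0.29), DHRS9 (-2.45 ± 0.69) and the fast myosin gene MYH6 (-1.02 ± 0.32). Other atrial members did not pass by edgeR: NPPA, the atrial natriuretic peptide gene, had -1.26 ± 0.59, MYL7 -0.61 ± 0.33, MYL4 -0.16 ± 0.26 and KCNJ3 -0.03 ± 0.21. The score was 5.40, 4.39 and 4.53 in knockdown 1, 2 and 3 and 5.59, 5.86 and 6.67 in control 1, 2 and 3. Camera gave an adjusted p of 2.73e-07 (median -1.31) and called the list under every left-out library, with adjusted p = 0.572 with an estimated correlation. The count of 7 became 13 without knockdown 1, 2 without knockdown 2 or knockdown 3, 3 without control 2, 4 without control 3 and 14 by weighted limma-voom. Of the 18 members, 13 are in another list, and knockdown 2 and 3 also had the lowest fibroblast scores.

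Ventricular markers were higher as a list by camera (17 genes; adjusted p = 0.0323; median 0.39), with adjusted p = 0.763 with an estimated correlation, and 0 members passed over the list alone (4 without knockdown 1, 1 without control 1, 6 without control 2, 5 by DESeq2, 4 with no filter, 3 with the block, 8 by weighted limma-voom) or over all genes. LBH, a transcription cofactor gene, had 1.0 ± 0.29, the fatty acid transporter gene CD36 -1.94 ± 0.57, the ventricular light chain gene MYL2 -0.09 ± 0.28 and IRX4, a ventricular transcription factor gene, 0.65 ± 0.35. Scores overlapped, at 4.95 to 5.35 in the knockdown and 4.59 to 5.31 in the controls, and the call ended without knockdown 3 (0.103), control 1 (0.305) or control 3 (0.118). The contractile program as a whole showed no call: the sarcomere list had a median of -0.04 over 27 genes (adjusted p = 0.506), calcium handling -0.05 over 18 (0.618), cardiomyocyte maturation -0.09 over 28 (0.621) and fetal and stress genes -0.20 over 17 (0.964). The means were -0.24, -0.29, -0.29 and -0.07 in the same order. By edgeR, 6 sarcomere members were lower and 0 higher at an unadjusted p under 0.05. Without control 1 the sarcomere list was called lower (0.00752), as was the maturation list (0.00589). Members of these lists, given as values, included MYPN (-1.09 ± 0.28), the calcium pump gene ATP2A2 (-0.90 ± 0.26), the sodium-calcium exchanger gene SLC8A1 (-0.57 ± 0.27), the adrenergic receptor gene ADRB1 (-2.62 ± 0.62) and SMYD1 (0.68 ± 0.21). MYH7 had -0.36 ± 0.41, TNNT2 0.11 ± 0.22, TNNI1 0.38 ± 0.23, TNNI3 -1.12 ± 0.41 and NPPB 1.06 ± 0.48. None of the 10 genes from MYPN to NPPB passed edgeR's quasi-likelihood test over all genes or over a list alone. Over all genes DESeq2 called MYPN, ATP2A2 and ADRB1, and weighted limma-voom MYPN, ATP2A2, SMYD1 and TNNI3. Over the list alone the sarcomere, calcium handling and maturation lists had 0 by edgeR, but 6, 1 and 5 by DESeq2, 4, 2 and 3 with no filter, 10, 5 and 9 by weighted limma-voom, 7, 3 and 8 without knockdown 1 and 3, 1 and 7 without control 1. The sarcomere and maturation lists had 1 each without control 2, and the maturation list 2 with the block.

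Cardiac transcription factors were lower by camera (25 genes; adjusted p = 0.00422; median -0.32), with adjusted p = 0.572 with an estimated correlation. The score was 4.84, 4.33 and 4.34 in knockdown 1, 2 and 3 and 5.19 to 5.62 in the controls, lowest in the libraries with the lowest fibroblast scores. Adjusted over the list alone, 6 fell and 0 rose, against 0 over all genes; among those that fell were TBX5, TBX3, GATA6 (-0.71 ± 0.19), HEY1 and NR2F2. That count was 15 without knockdown 1, 0 without knockdown 2, 3 without knockdown 3, 1 without control 3, 10 by limma-voom and 17 by weighted limma-voom, and the camera call ended without control 2 (0.113) and without the 17 members shared with other lists (0.943). Ion channels and gap junctions were lower by camera (25 genes; adjusted p = 0.0488; median -0.15), with adjusted p = 0.572 with an estimated correlation. In that list 6 fell and 1 rose when adjusted over the list alone, 7 in all against 0 over all genes. HCN4, CACNA1D, CACNA1G, GJA5 and GJC1 were among those that fell, and KCNJ2, the inward rectifier that sets the resting potential, rose (1.58 ± 0.42). The count was 3 without knockdown 2 or control 2, 2 without knockdown 3 or control 3 and 13 by weighted limma-voom. The score was 3.67, 3.43 and 3.66 in knockdown 1, 2 and 3 and 3.83 to 4.10 in the controls. Knockdown 3, which had the lowest fibroblast score, thus lay close to knockdown 1. The camera call ended without knockdown 1 (0.182), knockdown 2 (0.0964), control 2 (0.201) or control 3 (0.114), and without shared members (0.934).

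Genes near atrial fibrillation association signals were lower by camera (39 genes; adjusted p = 0.0248; median -0.17), with adjusted p = 0.572 with an estimated correlation. Their scores of 6.10, 5.82 and 5.97 in knockdown 1, 2 and 3 were also lower in knockdown 2 and 3, the libraries with the lowest fibroblast scores, against 6.26 to 6.52 in the controls. Adjusted over the list alone, 5 fell and 0 rose, against 0 over all genes; among those that fell were HCN4, TBX5, TBX3 and SYNE2, which encodes a nuclear envelope protein (-0.85 ± 0.20). The count was 13 without knockdown 1, 2 without knockdown 2 or control 3, 9 with no filter or with the block and 18 by weighted limma-voom. The camera call ended without knockdown 1 (0.0517), knockdown 2 (0.0767), control 2 (0.157) or control 3 (0.0960), and without the 22 members shared with other lists (0.131).

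**Figure D3:**
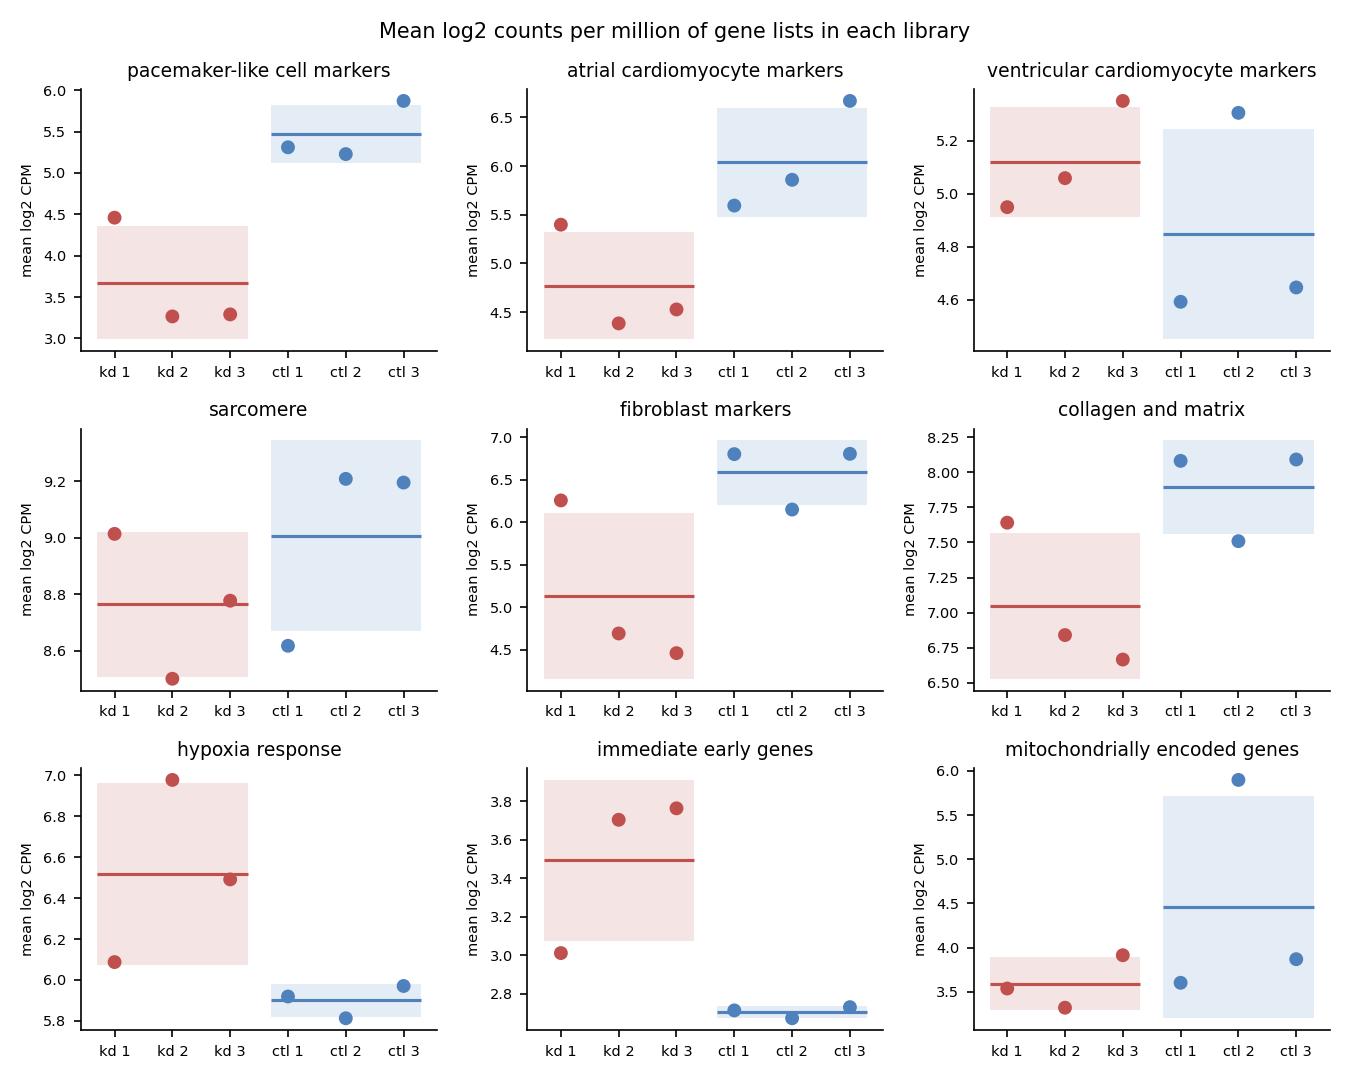
Mean log2 CPM of the members of fixed gene lists in each library, with a point per library (kd, knockdown; ctl, control), the group mean as a line and ± 1 SD as a band. The pacemaker-like score lies at 3.27 to 4.46 in the knockdown and 5.23 to 5.87 in the control, and the fibroblast score of knockdown 1 (6.25) lies within the controls (6.15 to 6.80).

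Fibroblast markers were lower in knockdown 2 and 3. Of 19 members, 3 fell and 1 rose when adjusted over the list alone, against 0 over all genes. PDGFRA, a receptor of mesenchymal cells (-1.68 ± 0.35), the matrix gene FBLN1 (23.1 ± 5.05 against 51.5 ± 17.3 CPM; -1.16 ± 0.27) and the secreted WNT inhibitor gene SFRP1 (-1.59 ± 0.36) fell, and POSTN, a matrix protein gene of activated fibroblasts, rose (1.01 ± 0.22). COL1A1 did not pass by edgeR, at 571, 145 and 82.1 CPM in knockdown 1, 2 and 3 against 534 to 1675 CPM in the controls (-2.05 ± 0.86). Camera gave an adjusted p of 7.43e-06 (median -1.67), called under every left-out library, and adjusted p = 0.572 with an estimated correlation. The count of 4 became 16 without knockdown 1 and 0 without knockdown 2 or knockdown 3. It was 11 by DESeq2 or limma-voom (1 higher, 10 lower), 8 with the block, 2 with no filter and 15 by weighted limma-voom, and 12 of the 19 members are in another list.

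Collagen and matrix genes were lower by camera (35 genes; adjusted p = 8.94e-06; median -0.67), under every left-out library too, with adjusted p = 0.572 with an estimated correlation. Adjusted over the list alone, 3 fell and 3 rose, against 0 over all genes: the elastin gene ELN (-2.19 ± 0.42), COL12A1 (-1.26 ± 0.30) and the proteoglycan gene BGN (-1.84 ± 0.44) fell, while POSTN, the fibrillin gene FBN2 (0.89 ± 0.25) and THBS1 (0.80 ± 0.22) rose. The count of 6 became 26 without knockdown 1, 15 without control 2, 1 without control 1 and 0 without knockdown 2, knockdown 3 or control 3. With all libraries kept, the balance of 3 higher and 3 lower shifted to 3 and 7 with upper quartile factors, 3 and 10 by limma-voom, 3 and 11 by DESeq2 or with the block, 5 and 8 with no filter, and 5 and 24 by weighted limma-voom. WNT signalling genes were lower by camera (24 genes; adjusted p = 0.0442; median -0.61), with adjusted p = 0.572 with an estimated correlation. FZD1 (-0.66 ± 0.15), SFRP1, RSPO3 (-1.03 ± 0.28), WNT4 (-2.32 ± 0.64), WNT5A (-0.66 ± 0.19) and WNT11 (-0.87 ± 0.28) fell and FRZB, another secreted inhibitor gene, rose (2.30 ± 0.52) when adjusted over the list alone, 7 against 0 over all genes. That count was 13 without knockdown 1, 1 without control 1, 0 without knockdown 2, knockdown 3 or control 3 and 15 by weighted limma-voom. The camera call ended without knockdown 2 (0.0842), knockdown 3 (0.0807), control 1 (0.225) or control 2 (0.151), and without shared members (0.110). The WNT score was 4.02, 3.03 and 2.99 in knockdown 1, 2 and 3 and 3.78 to 4.36 in the controls, and the matrix score of knockdown 1 was 7.64, against 6.84 and 6.66 in knockdown 2 and 3 and 7.51 to 8.09 in the controls.

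Endothelial and endocardial markers were higher by camera (20 genes; adjusted p = 0.0117; median 0.93), under every left-out library too, with adjusted p = 0.572 with an estimated correlation. No member passed over the list alone (0 of 20): VWF, the endothelial clotting factor gene, had 2.57 ± 0.64, PECAM1 1.88 ± 0.64, CDH5 1.47 ± 0.54 and FLT1 -1.11 ± 0.31. Scores were 1.81, 2.15 and 2.33 in knockdown 1, 2 and 3, highest where fibroblast scores were lowest, and 1.09 to 1.83 in the controls. That count of 0 became 6 without knockdown 1, 1 without control 1 and 9 without control 2. It was 2 with upper quartile factors or library size only, 5 by DESeq2 or with no filter, 4 with the block and 14 by weighted limma-voom. Epicardial and mesothelial markers were not called (16 genes; adjusted p = 0.0663; median -1.24), with scores of 6.28, 3.48 and 3.0 in knockdown 1, 2 and 3 and 6.39, 4.40 and 5.30 in control 1, 2 and 3. The list was called lower without knockdown 1 (7.21e-06) or control 2 (0.0166), and with all libraries under upper quartile factors (0.0471) or the block (0.00414). SEMA3D had -0.67 ± 0.26 and KRT19 0.54 ± 0.20. Smooth muscle and pericyte markers (median -0.11; adjusted p = 0.269) held 2 genes that passed over the list alone, the potassium channel subunit gene ABCC9 (-1.12 ± 0.28) and the actin nucleator gene LMOD1 (0.51 ± 0.14). That count was 6 without knockdown 1, 1 without control 1 and 0 without any other library, and 1 by limma-voom, 0 with the block and 7 by weighted limma-voom.

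Of 19 hypoxia-response genes, 8 rose and 0 fell when adjusted over the list alone, against 0 over all genes. The 8 were ANGPTL4 (1.70 ± 0.38), the mitophagy receptor gene BNIP3 (1.06 ± 0.24), AK4 (0.73 ± 0.20), PFKFB4 (1.76 ± 0.46), ANKRD37 (2.17 ± 0.58), the glucose transporter gene SLC2A1 (295 ± 160 against 102 ± 16 CPM; 1.54 ± 0.42), the histone demethylase gene KDM3A (1.18 ± 0.37) and the lactate dehydrogenase gene LDHA (0.79 ± 0.26). The score was 6.09, 6.98 and 6.49 in knockdown 1, 2 and 3 and 5.81 to 5.97 in the controls. Knockdown 2 and 3 also had the lowest fibroblast scores (4.69 and 4.46, against 6.25 in knockdown 1) and matrix scores. Camera gave an adjusted p of 6.11e-05 (median 0.71), called under every left-out library, and adjusted p = 0.572 with an estimated correlation. The count of 8 became 16 without knockdown 1, 3 without control 2, 1 without control 1 and 0 without knockdown 2, knockdown 3 or control 3, and was 3 by limma-voom and 15 by weighted limma-voom. Glycolysis genes were higher by camera (25 genes; adjusted p = 4.49e-05; median 0.50), under every left-out library too, with adjusted p = 0.646 with an estimated correlation and scores of 7.85, 8.55 and 8.36 in knockdown 1, 2 and 3 against 7.61, 7.92 and 7.86 in control 1, 2 and 3, so that knockdown 1 overlapped the controls. None passed over the list alone by edgeR (0, and 14 without knockdown 1, 7 by DESeq2, 6 with no filter or with the block and 13 by weighted limma-voom); the lactate transporter gene SLC16A1 had 0.64 ± 0.18 and PGK1 0.63 ± 0.21.

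Among 18 immediate early genes, which respond within minutes to growth factors and stress, 8 rose and 0 fell when adjusted over the list alone, against 0 over all genes: ATF3 (1.40 ± 0.26), FOS (1.98 ± 0.45), FOSB (2.48 ± 0.70), JUN (0.57 ± 0.20), EGR1 (0.94 ± 0.28), NR4A1 (20.2 ± 10.4 against 5.73 ± 1.28 CPM; 1.82 ± 0.45), NR4A3 (1.59 ± 0.42) and DUSP1 (0.69 ± 0.21). The score was 3.01, 3.70 and 3.76 in knockdown 1, 2 and 3, above the controls at 2.67 to 2.73. Knockdown 1, nearest the controls, was the knockdown library with the highest fibroblast score (6.25, against 4.69 and 4.46). Camera gave an adjusted p of 4.71e-06 (median 0.64), called under every left-out library, and adjusted p = 0.572 with an estimated correlation. The count of 8 became 1 without control 1, 2 without control 2 or control 3, 0 without knockdown 2 or knockdown 3, and 1 by limma-voom. NF-kB and cytokine response genes were higher by camera (15 genes; adjusted p = 0.00434; median 0.42), under every left-out library too, with adjusted p = 0.572 with an estimated correlation. RELB, a subunit of the factor (1.61 ± 0.29), its feedback inhibitor TNFAIP3 (1.78 ± 0.37) and the adhesion gene VCAM1 (0.84 ± 0.20) rose when adjusted over the list alone (3, against 0 over all genes). That count was 6 without knockdown 1, 5 without control 2, 1 without control 1 or control 3, and 5 by DESeq2, with no filter or by weighted limma-voom. The NF-kB score was 2.66, 2.48 and 2.36 in knockdown 1, 2 and 3 and 1.84 to 2.30 in the controls. It was highest in knockdown 1, which had the highest fibroblast score among the knockdown libraries. Heat shock genes were higher by camera (14 genes, adjusted p = 0.00713, median 0.24), with adjusted p = 0.572 with an estimated correlation, and the call ended without control 1 (0.0756). Their score was 7.10, 7.32 and 7.45 in knockdown 1, 2 and 3 and 6.93 to 7.09 in the controls. It was highest where fibroblast scores were lowest. The chaperone gene HSPH1 rose when adjusted over the list alone (0.74 ± 0.18; 1 gene, 3 without knockdown 1, and 0 without knockdown 2, knockdown 3, control 2 or control 3), and HSPA1B had 0.77 ± 0.26. With all libraries kept that count was 0 with upper quartile factors, library size only or protein-coding genes only, 2 by DESeq2, with no filter or with the block, and 5 by weighted limma-voom. Cholesterol synthesis genes were higher by camera (18 genes; adjusted p = 0.00434; median 0.29), with adjusted p = 0.649 with an estimated correlation and overlapping scores of 6.18 to 6.54 in the knockdown and 5.87 to 6.26 in the controls. MVK had 0.50 ± 0.20 and SC5D 1.01 ± 0.45, 0 passed over the list alone (1 higher without control 2, 1 lower with no filter, 4 higher by weighted limma-voom), and the call ended without control 1 (0.109).

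**Figure D4:**
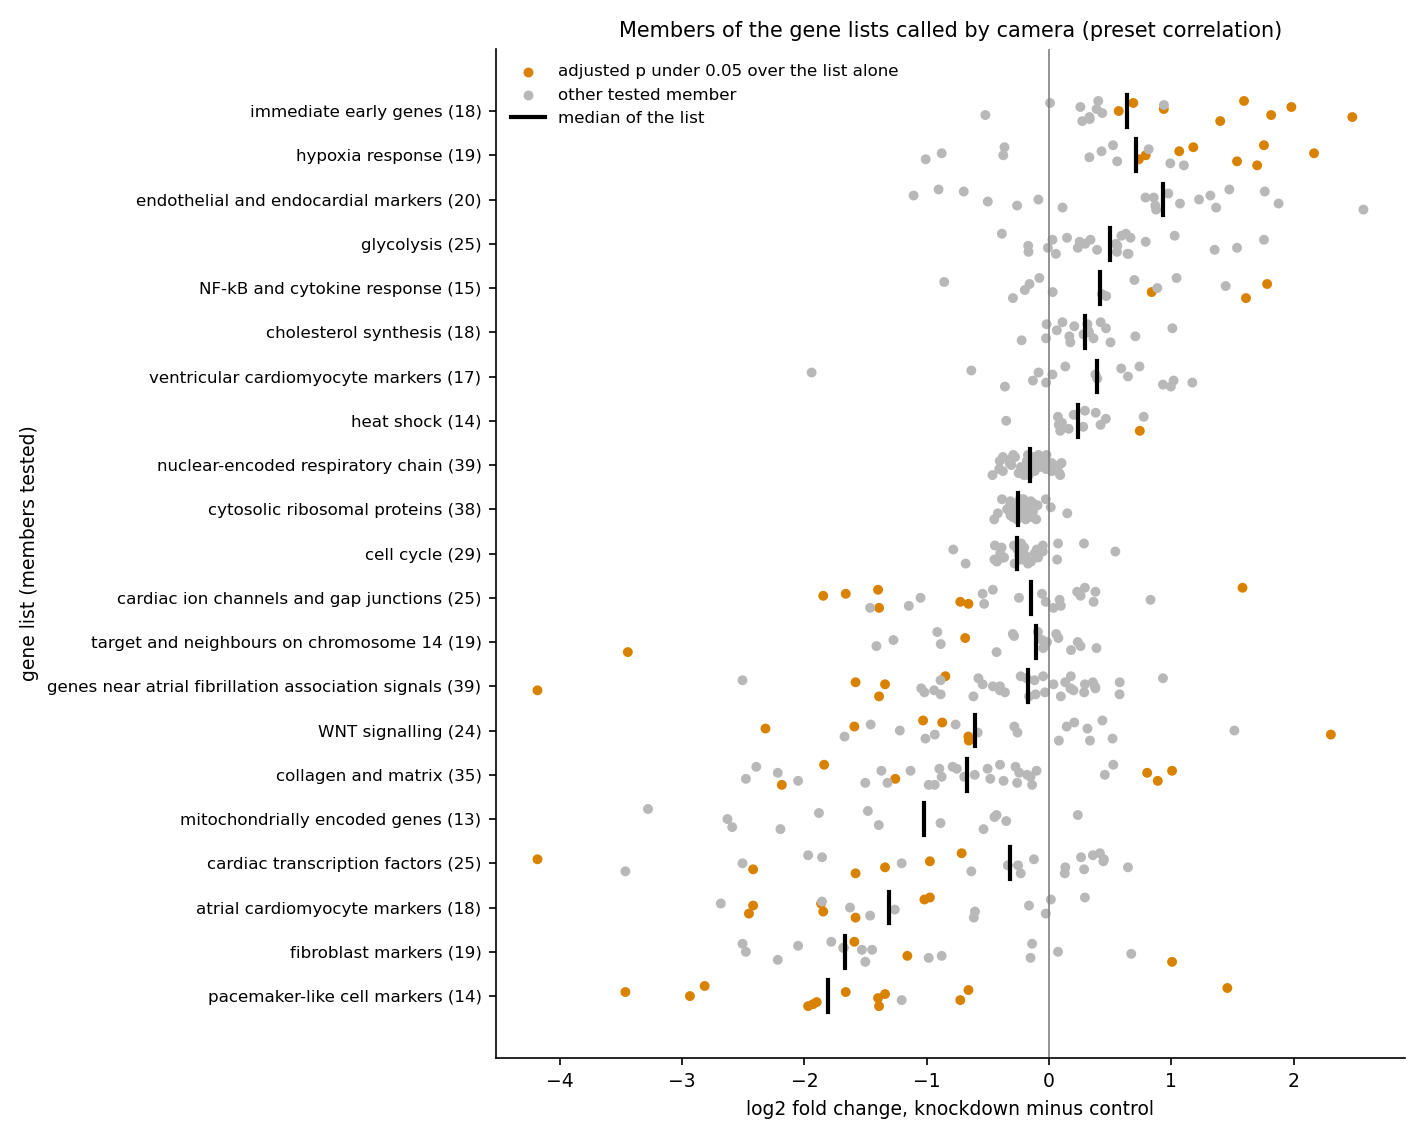
Log2 fold changes (knockdown minus control) of the members of each list called by camera, with members that passed over the list alone in orange, other members in grey, the median of the list's log2 CPM differences as a bar, and lists ordered by their mean. The medians run from -1.81 for pacemaker-like markers to 0.93 for endothelial and endocardial markers.

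Ribosomal, mitochondrial and cell cycle lists were also lower by camera, and edgeR called 0 of their members over the list alone. Cytosolic ribosomal protein genes were lower by camera (38 genes; adjusted p = 2.88e-05; median -0.25), with 36 of 38 below 0, RPS2 at -0.45 ± 0.19 and RPS15 at -0.32 ± 0.15, and 21 passed over the list alone by weighted limma-voom. The list had adjusted p = 0.857 with an estimated correlation. The score was 9.33 in knockdown 1 and 9.04 and 8.78 in knockdown 2 and 3, which had the lowest fibroblast scores, against 9.25 to 9.33 in the controls. The call ended without knockdown 3 (0.0933). Mitochondrially encoded genes were lower by camera (13 genes; adjusted p = 0.00422; median -1.03), with adjusted p = 0.785 with an estimated correlation. Their score was 5.90 in control 2 and 3.32 to 3.91 in the other 5 libraries, and without control 2 the median was -0.23 and the adjusted p 0.165; MT-ND4L had -2.20 ± 0.86 and MT-CO1 -0.43 ± 0.18, and 5 members passed over the list alone by DESeq2. Nuclear-encoded respiratory chain genes were lower by camera (39 genes; adjusted p = 0.0247; median -0.15), with adjusted p = 0.928 with an estimated correlation and NDUFS7 at -0.46 ± 0.18. The scores overlapped, at 6.59, 6.42 and 6.40 in knockdown 1, 2 and 3 and 6.29, 6.75 and 6.80 in control 1, 2 and 3. That call ended without knockdown 2 (0.108), knockdown 3 (0.166), control 2 (0.466) or control 3 (0.562). Cell cycle genes were lower by camera (29 genes; adjusted p = 0.0248; median -0.26), with adjusted p = 0.919 with an estimated correlation. The score was 4.82, 4.10 and 4.09 in knockdown 1, 2 and 3 and 4.42 to 4.82 in the controls, lowest in the libraries with the lowest fibroblast scores. KIF20A had -0.68 ± 0.28 and UBE2C -0.78 ± 0.33. The call ended without knockdown 2 (0.359), knockdown 3 (0.421) or control 1 (0.361), and 10 members passed over the list alone without knockdown 1 and 5 by weighted limma-voom.

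In all, camera called 21 of 45 lists, 8 higher and 13 lower, and 9 of the 21 were called under every left-out library. With an estimated correlation 0 were called, with adjusted p-values of 0.572 to 0.928 for the 21, and fry called 0 (smallest adjusted p = 0.180). The 24 lists not called had adjusted p-values of 0.0663 to 0.964 by camera.

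Some of the lists not called still held genes that passed over the list alone, against 0 over all genes. In NOTCH signalling (median -0.18; adjusted p = 0.682) the ligand gene DLL4 (2.23 ± 0.56) and the target NRARP (1.34 ± 0.42) rose, and HEY1 and the ligand gene JAG1 (-0.88 ± 0.26) fell. The 4 became 0 without knockdown 2, knockdown 3, control 1 or control 3, and 0 with protein-coding genes only. Among cartilage and bone markers, COL9A1 (-1.68 ± 0.31), COL2A1 (-1.49 ± 0.45) and SOX9 (-0.79 ± 0.27) fell and HAPLN1 (1.05 ± 0.35) rose. Those 4 became 2 without knockdown 3 or control 1, 1 without knockdown 2 or control 3, and 7 by weighted limma-voom. That list's median was 0.50 but its mean was -0.10 and camera's direction was lower (adjusted p = 0.682). In matrix proteases and inhibitors (median -0.14; 0.951), 3 genes rose, among them the collagenase gene MMP1 (3.18 ± 0.73) and MMP15 (0.72 ± 0.20). That count of 3 became 10 without knockdown 1, 1 without control 3 and 0 without any other library. It was 5 by DESeq2, 0 by limma-voom, 6 with the block and 8 by weighted limma-voom. Among neuronal markers (median -0.38; 0.220, and called lower without knockdown 2 at 0.0368, knockdown 3 at 0.0152 or control 1 at 0.0232), GAD1 fell (-2.79 ± 0.64) and NEFM rose (3.11 ± 0.82). Their count of 2 became 4 without knockdown 1, 1 without control 1 and 0 without any other library, and was 4 by DESeq2, with the block or by weighted limma-voom and 1 with a CPM of at least 1. In the desmosome, costamere and intercalated disc list, XIRP1 rose and TLN2 fell (-0.77 ± 0.15). The list's count of 2 became 1 without knockdown 2 or knockdown 3, and was 4 by DESeq2, 5 with no filter and 10 by weighted limma-voom. That list had a median of 0.04, a mean of -0.02 and a higher direction by camera (0.682). XIRP1 also passed in the fetal and stress list, whose count of 1 became 6 without knockdown 1, 3 without control 1 or control 3 and 2 without control 2, and was 6 by DESeq2, 7 with no filter, 5 with the block and 11 by weighted limma-voom. In the unfolded protein and integrated stress response list (median -0.06, mean 0.05, higher by camera; 0.621), ATF3 rose and DDIT4 had 0.98 ± 0.28. The count of 1 became 4 without knockdown 1 and 0 without knockdown 2 or knockdown 3, and was 2 by DESeq2, 3 with no filter and 5 by weighted limma-voom.

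The remaining lists held no gene that passed edgeR's test over the list alone with all libraries, a count of 0 that moved in some settings. For TGF-beta response it was 11 (4 higher, 7 lower) without knockdown 1, 2 without control 3, 7 with the block, 6 by DESeq2, 3 with no filter and 14 by weighted limma-voom. It was 1 without knockdown 1 for histones, epithelial and pluripotency markers, 1 without control 1 for skeletal muscle and 1 without control 3 for neural progenitor markers. It was 3 with the block and 1 with no filter for epithelial markers, 1 by DESeq2 for fatty acid oxidation and for endoderm markers, and 1 to 5 by weighted limma-voom for interferon, endoderm, epithelial and neural progenitor lists. Replication-dependent histones had a median of -0.19 (adjusted p = 0.134 by camera) and were called lower without knockdown 1 (0.00612) or control 2 (0.000774), or with the block (0.0241). TGF-beta response genes had -0.12 (0.363), with CCN2 at 0.79 ± 0.23, and antigen presentation 0.10 (0.284), with HLA-C at 0.46 ± 0.14. Definitive endoderm, liver and gut markers had -0.66 (0.265), with APOA1 at -1.90 ± 0.71 and SOX17 at 1.76 ± 0.76. Fatty acid oxidation genes had a median of 0.0025, a mean of -0.02 and a higher direction (0.857), with CPT1B at 0.68 ± 0.28, epithelial markers -0.20 (0.904), with EPCAM at -1.13 ± 0.69, and interferon response -0.05 (0.941), with ISG15 at 0.56 ± 0.20. The CRISPR interference cofactors, which carry out silencing by the KRAB domain, had 0.06 (0.926), with CHD4 at -0.21 ± 0.13. Pluripotency markers had a median of 0.01 and a mean of -0.04, with a lower direction (0.926) and DNMT3B at -0.58 ± 0.32, and p53 targets a median of 0.02, a mean of -0.0043 and a higher direction (0.941), with TP53INP1 at -0.35 ± 0.13. Neural progenitor and glial markers had 0.0048 (0.941), with NES at -0.46 ± 0.22, and skeletal muscle markers 0.27 (0.941), with MYOG at -0.95 ± 0.42. Of 19 blood and macrophage markers, 2 were kept, RUNX1 (-0.55 ± 0.55) and PTPRC (0.45 ± 0.46), too few for a test.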

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

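The weighted limma-voom fit, the fit without knockdown 1 and control 2 together, the lists without shared members and upper quartile scaling for lists were chosen after the result was seen. The count of genes changed was 0 under 10 settings that kept all libraries and their weights, 363 by DESeq2's own test and 417 with no low count filter in edgeR. Among the 10, the stricter adjusted p and the fold threshold used the main fit, so they could only give 0. The count was 1478 by weighted limma-voom and 2581 without knockdown 1 and control 2. Leaving out single libraries gave 0 to 554. The change of LINC01629 kept its sign in every setting that tested it, from -3.79 to -3.11, and passed over all genes at -3.23 by weighted limma-voom (adjusted p = 0.0212) and -3.26 without knockdown 1 and control 2 (adjusted p = 0.0424); its adjusted p lay between 0.0212 and 0.9995 over the settings. DESeq2 gave it no adjusted p, and the filter of a CPM of at least 1 and the limit to protein-coding genes removed it, so these gave no value. For its neighbours the count was 3 by weighted limma-voom, 3 without knockdown 1 and control 2, and 0 to 1 with single libraries left out. For lists, camera called 16 to 22 under the other scalings, filters, prior count, block and left-out libraries, 0 with an estimated correlation and 0 by fry. The cause of these moves was not tested, except that the fits without libraries had fewer samples.

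Numbers 1 to 3 are shared by the groups, but same-numbered libraries did not all correlate (-0.061 for number 3), so the block tests only a shared number. The common dispersion was 0.0590 with the block and 0.0920 without it. A shared origin of same-numbered libraries was therefore not excluded. With the block edgeR called 0 genes, with 2492 at an unadjusted p under 0.05, and camera called 22 lists; it ended the call of the nuclear-encoded respiratory chain (0.0691) and called epicardial markers (0.00414) and replication-dependent histones (0.0241).

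Of the 112 genes named by the rule beside LINC01629, 68 passed over all genes in 1 or more settings, always with the sign reported. In 13 genes the sign changed between settings that both left the gene short of the threshold, as it did in 16 lists. Of the 21 lists called, all lost the call in 1 or more settings, the estimated correlation and fry among them, and 7 lists not called gained it. The count of members past the threshold over the list alone rose by over 1.5 times in 40 lists and fell by over 1.5 times in 20, in 1 or more settings each. The precision for LINC01629 is limited by its 4 knockdown counts.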

Other observations

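Some genes outside the fixed lists, chosen after their values were seen, had separated groups. The metallothionein genes MT1X and MT1E, which bind zinc and copper, were higher in each knockdown library than in any control: MT1X was at 11.9 ± 5.48 CPM (SD, n = 3) in the knockdown and 2.20 ± 1.90 CPM in the control (log2 fold change 2.45 ± 0.66), beside MT1E at 9.52 ± 4.51 and 1.33 ± 0.148 CPM. MT2A overlapped between the groups (0.58 ± 1.68). DLK1, a NOTCH-related gene expressed from the paternal copy, was at 9.13, 6.25 and 3.93 CPM in knockdown 1, 2 and 3 and at 28.1, 32.5 and 110 CPM in control 1, 2 and 3 (-3.14 ± 0.67). H19, a non-coding RNA expressed from the maternal copy, had 0.68 ± 0.19, IGF2, its paternally expressed neighbour, 0.42 ± 0.18, and PEG10 1.55 ± 0.62. None passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p of 0.368 for MT1X, 0.337 for DLK1 and 0.355 for H19). DESeq2 gave these genes adjusted p-values of 0.00237, 3.03e-07 and 0.0144, but in the simulation it made 53 false calls against 8 by edgeR. The simulation drew independent genes with edgeR's dispersions, so it does not tell whether these calls are false.

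The tests with the fibroblast score as a covariate, of other scalings and of other splits were written before their results were seen; those of cardiomyocyte share, of knockdown 1 and of control 2 were chosen after the result was seen.

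Pacemaker-like and atrial markers were lower together. A lower share of cardiomyocytes in the knockdown is argued against as the whole cause by the sarcomere list. The list's mean difference in log2 CPM was -0.24. By edgeR, 6 members were lower and 0 higher at an unadjusted p under 0.05. The list's median log2 CPM difference stayed between -0.29 and 0.07 with each library left out. Its median log2 fold change was -0.054, with a range of 2 SE from -0.39 to 0.28. That range is over the list's genes taken as independent, though their estimated correlation was 0.423. It therefore does not measure the spread between libraries. Camera called the list lower without control 1 (-0.21, adjusted p = 0.00752), so that a small difference in share stays open. Scaling was not tested by the pacemaker-like median of -1.79 or lower under the other scalings, since these moved the median of all genes only between -0.018 and 0.005. Fewer fibroblasts stay open as a candidate explanation. With the fibroblast score as a covariate, the group coefficient of the pacemaker-like score was -0.82 ± 0.31 (SE), against -1.80 ± 0.44 without it. That of the atrial score was -0.51 ± 0.58 against -1.27 ± 0.45. The range of 2 SE for the pacemaker-like score with the covariate, -1.44 to -0.20, is narrower than a 95% interval with so few libraries. It therefore does not show that a group effect remains. With 6 libraries, and a covariate that itself differs between the groups, the share of the change that goes with it cannot be told apart from silencing of LINC01629, the biological explanation that the design gives.

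Knockdown 1 lay nearer the controls than knockdown 2 and 3. Weaker silencing in it stays open: its LINC01629 level of 0.0478 CPM is 1 count, whose interval reaches 0.266 CPM, above that of the other knockdown libraries together (0.0160 to 0.227 CPM) and into that of control 1. A swap with a control is argued against by the lowest control, at 0.506 CPM (0.243 to 0.930), above the knockdown libraries together (0.0672 CPM, 0.0183 to 0.172). Its fibroblast score of 6.25, within the 6.15 to 6.80 of the controls and above the 4.69 and 4.46 of the other knockdown libraries, is consistent with a difference in cell content between cultures. That explanation was found from the same values and is a hypothesis only.

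The lower mitochondrially encoded list rests on control 2: without it the median was -0.23 (adjusted p = 0.165, against 0.00422 with all libraries). Control 2 also had 23.4% of genes of low mean count at 0, against 7.0% to 11.1% in the other libraries. The variance across those genes over their mean was 19.2 in control 2 and 3.60 to 5.43 in the other libraries. Control 2 had 2386 genes with 1 or 2 counts, against 4682 to 6000. No explanation of these values, technical or biological, was tested for this library.

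The 6 libraries make 10 splits into equal groups, which are too few for a share under 0.05. The real split called 0 genes and the highest other 509; with a real count of 0, all 10 splits are as large by construction, which says nothing about chance. That other split set knockdown 1, control 1 and control 3 against knockdown 2, knockdown 3 and control 2, with 4058 genes at an unadjusted p under 0.05, which points to a structure of the samples other than the groups. For lists the real split called 21 and the highest other 20 (1 of the 10 splits as large), and for neighbours 0 and 1 (again 10 by construction).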
